A study of Homo sapiens
Mus musculus with 21 samples.

How the data were processed

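The study measured polyA-selected RNA, by paired-end sequencing, in subcutaneous tumours grown in athymic nude mice, which lack most T cells. The tumours came from T24, a human bladder cancer cell line, engineered to express human Nectin-4 (symbol NECTIN4, listed under its older symbol PVRL4), a cell adhesion protein of epithelial cells. One group of mice received enfortumab vedotin (EV), an antibody against Nectin-4 that carries the microtubule-disrupting drug MMAE, as a single intraperitoneal dose of 3 mg/kg. A second group received the same dose of a control antibody-drug conjugate (control ADC), an IgG carrying MMAE, and the last group was untreated. Treatment was on day 15 after implantation, at about 200 mm3, and the tumours were taken 5 days later, per the labels' protocols. There were 7 mice per group and 1 library per mouse, 21 libraries in all. P-values of single genes and of library measures therefore set a difference against the variation between mice. Camera's p-values for gene lists also rest on a preset correlation between genes, given below. The labels give no sequencing batch or date.

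Per the submitters' processing notes, cutadapt, STAR and RSEM were used with the builds hg38 and mm10; their versions, the annotation and the way reads were divided between the species are not given in the sources used here. The deposited table holds 81930 gene symbols for 21 libraries as TPM (a read count divided by transcript length and by the library's total). It is recorded here as a signal because the authors' deposited columns sum to between 2.06 and 7.75 times the total of a TPM column. Mouse-style names alone sum to between 995148 and 998429 per library and human-style names to between 883797 and 989632. Each species therefore carried a TPM total of its own, and a symbol that exists with the same spelling in both species has a single row. The H19 row reached from 62005 to 5768760 and exceeded the total of a TPM column in 12 libraries, so it is not a TPM in the usual sense. TPM keep no read depth, so the depth of each library is unknown and no counting intervals or floors are given. Because each species has a fixed total, the share of mouse RNA in a tumour cannot be read from the table. The comparison of that share, planned before the data were examined, and the fits with it as a covariate were not run.

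Rows were given to human where the symbol matched a RefSeq symbol or synonym (27459 rows) or had the human mitochondrial prefix (37 rows), and to mouse by the spelling of mouse symbols (37059 rows). The 299 names that both species can hold and 17076 clone names and small RNA families were left out. All 21 columns were matched to a sample by name. No genome was used, so no coordinates are given. Within each library, each species was rescaled to the same total. The human sum before rescaling went with the groups. It ran from 964495 to 989632 in untreated libraries. In control ADC it ran from 918016 to 930882, apart from 968537 in control ADC 7. In EV it ran from 883797 to 922593, apart from 969848 in EV 3. Rescaling therefore raised human values more in most ADC libraries. Genes with a mean of at least 1 TPM over all libraries were tested, which left 12582 human and 13415 mouse genes. Values were analysed as log2(TPM + 1), so that fold changes of genes near 1 TPM are understated. The linear model of limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend) was fitted to all 3 groups together, without covariates, for 3 comparisons: EV against control ADC, EV against untreated and control ADC against untreated. Errors of fold changes are standard errors of this model. P-values are two-sided and adjusted by Benjamini-Hochberg within species and comparison, and a gene was called at an adjusted p under 0.05. The design assumed TPM, and the deposited unit required no other test.

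The 17 human and 24 mouse gene lists were fixed before the data were examined. The human lists included interferon response, antigen presentation on MHC class I and class II, ER stress, danger signals, mitosis, DNA replication, tubulins, p53 targets, NF-kB genes, apoptosis, hypoxia, cholesterol synthesis, epithelial differentiation, mesenchymal genes and checkpoint ligands. The mouse lists covered macrophages, monocytes, neutrophils, dendritic, NK, B, T and mast cells, endothelium, fibroblasts, pericytes, adipocytes, skeletal muscle, skin, red cells, both interferon responses, both classes of antigen presentation, T cell costimulation, alternatively activated macrophages, chemokines, phagocytosis and proliferation. Of their symbols, 473 of 474 human and 499 of 502 mouse ones were found. Lists with at least 3 tested members were compared with the remaining genes of the species by camera with its preset inter-gene correlation of 0.01, adjusted over the lists of a species and comparison. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes, were run beside it. The estimate was above the preset, for example 0.52 for the human hypoxia list and 0.79 for the human mitosis list. With it camera called 0 lists in each comparison of either species. Calls by camera below are therefore those at the preset correlation. Camera's direction is relative to the other genes and can differ in sign from a list's median.

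The genes named were taken by a rule set before the data were examined. For EV against control ADC these were the 10 human genes that rose most and the 10 that fell most, and 6 and 6 mouse genes, among called genes with a mean of at least 5 TPM and a proper symbol; for the other comparisons 4 and 4 per species. From each list, members among the 4 with the smallest p were taken, and NECTIN4 always. Percentages of TPM from ribosomal protein genes and from mitochondrially encoded genes were compared by exact two-sided permutation tests of the difference in means, with Benjamini-Hochberg adjustment over the 12 tests (scipy 1.17.1); these measures were chosen after seeing the data.

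The tests across genes were tested on simulated data. For human genes, EV against control ADC (12582 genes), 12% of 50 genes changed by 0.5 on the log2 scale were called, 78% of 50 changed by 1 and 94% of 50 changed by 2. For mouse genes in the same comparison (13415 genes) the shares were 8%, 26% and 98%. The simulation drew genes independently, which real libraries do not do. Alternatives planned beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5 TPM, TPM as deposited, upper-quartile scaling, fits of only the 2 groups compared, the mouse number as a replicate block, library weights, and leaving out each library. Other settings were chosen after seeing the data. EV 3, control ADC 7 and untreated 5, the 3 libraries whose human profile lay most clearly with another group, were left out. Leaving out libraries by their profiles favours differences between the groups. The remaining settings were the ribosomal protein percentage as a covariate and scaling that sets each library's median log2 ratio to 0 (median-ratio scaling).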

Results

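Gene expression was measured in 21 xenograft tumours of T24 bladder cancer cells carrying human Nectin-4, 7 from untreated mice, 7 from mice given a control ADC and 7 from mice given EV. Human transcripts are taken to come from the tumour cells and mouse transcripts from the host cells within the tumour. Each was analysed against its own total. How reads were divided between the species is not given, and mouse reads assigned to human genes were not tested for. Within groups, pairs of libraries correlated across human genes with a median Pearson's r of 0.970 in untreated, 0.967 in control ADC and 0.954 in EV tumours, and across mouse genes with 0.906, 0.876 and 0.896. No pair held identical values. Read depth is unknown because TPM do not keep it.

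Transcripts of the drug's target, NECTIN4 (listed as PVRL4), were present in every group. Their mean was 130 ± 69.5 TPM (SD, n = 7) in untreated, 272 ± 77.5 in control ADC and 349 ± 151 in EV tumours. The table does not separate the introduced from the endogenous gene. NECTIN4 was higher than in untreated tumours after EV, by 1.44 ± 0.30 on the log2 scale (SE, limma, adjusted p = 0.00055), and after control ADC, by 1.16 ± 0.30 (limma, adjusted p = 0.0035). With the ribosomal protein percentage as a covariate neither was called, and the differences were −0.069 and 0.034. Between EV and control ADC the difference was 0.28 ± 0.30 (limma, adjusted p = 0.59).

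The tumours differed in broad features of their RNA. Ribosomal protein transcripts made up 32.9 ± 5.54% (SD, n = 7) of human TPM in untreated tumours, 22.8 ± 4.27% after control ADC and 19.5 ± 4.71% after EV. The difference from untreated passed the test for control ADC (exact permutation test, p = 0.0070, adjusted p = 0.0105) and for EV (exact p = 0.0012, adjusted p = 0.0035). The difference between EV and control ADC did not pass it (exact p = 0.206, adjusted p = 0.247). Mouse ribosomal protein transcripts followed the same order, at 28.5 ± 4.53%, 19.7 ± 3.97% and 15.9 ± 3.61%, with exact adjusted p of 0.0070 for control ADC and 0.0035 for EV against untreated and 0.115 between the ADC groups. Mitochondrially encoded transcripts, which encode parts of the respiratory chain, were highest after EV. They made up 7.18 ± 2.72% of human TPM after EV, 2.32 ± 1.02% after control ADC and 1.62 ± 1.13% in untreated tumours, and 6 of the 7 EV tumours lay above every control ADC tumour (exact p = 0.0012, adjusted p = 0.0035). In mouse transcripts the percentages were 16.1 ± 8.57, 5.37 ± 2.61 and 3.76 ± 2.25 (EV against control ADC, exact p = 0.0035, adjusted p = 0.0070). Between control ADC and untreated tumours neither mitochondrial difference passed the test (exact adjusted p = 0.247 for both species). In EV 3 and control ADC 7 the human ribosomal protein percentage was 29.2 and 32.0, within the range of untreated tumours, and in untreated 5 it was 22.6, within the range of control ADC tumours. Apart from untreated 5 the lowest untreated value was 30.1, above that of EV 3. Leaving out these 3 libraries, picked because their human profiles lay most clearly with another group, itself favours differences between groups. Without them all 12 differences passed the test. Human mitochondrial transcripts were then at 2.60 ± 0.76% after control ADC and 1.22 ± 0.37% in untreated tumours (SD, n = 6, exact adjusted p = 0.0052), mouse ones at 5.76 ± 2.62% and 2.99 ± 1.05% (0.015), and the ribosomal protein difference between EV and control ADC had an adjusted p of 0.012 in human and 0.0052 in mouse transcripts.

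**Figure D1:**
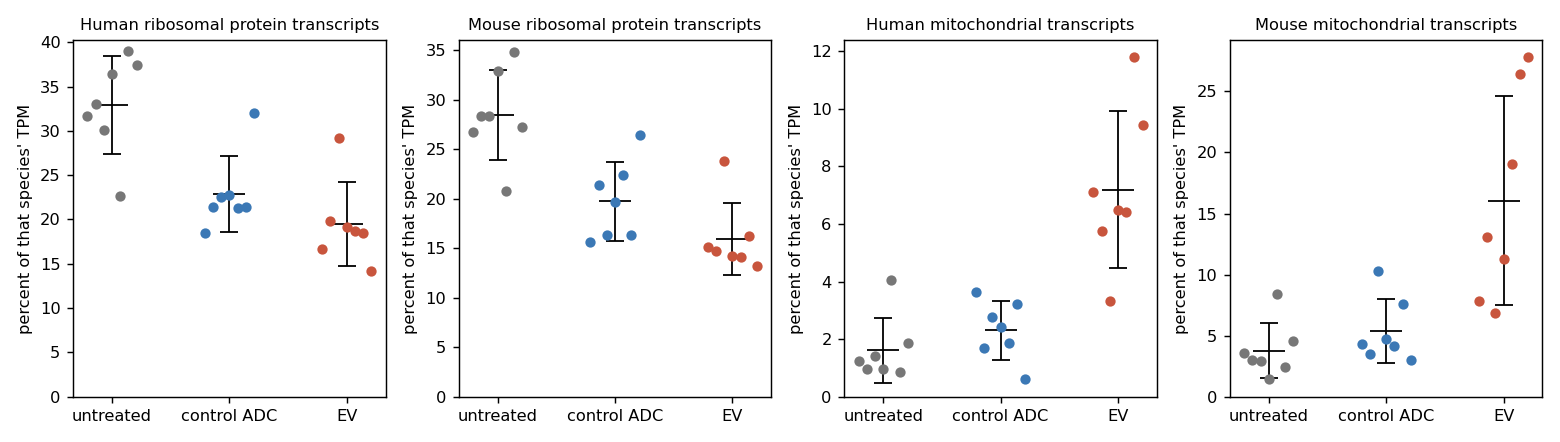
Percent of TPM taken by ribosomal protein and by mitochondrially encoded transcripts in each tumour, for human and mouse genes separately; points are tumours, bars the mean and SD of 7. Untreated tumours have the highest ribosomal protein means (32.9% human, 28.5% mouse) and EV tumours the highest mitochondrial means (7.18% human, 16.1% mouse).

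EV and control ADC carry the same drug, and only the antibody of EV is directed against Nectin-4. In tumour cells the clearest fall was in genes of the hypoxia response. NDRG1, a gene induced by low oxygen, fell by 2.73 ± 0.49 on the log2 scale (SE, limma, adjusted p = 0.0069), from 593 ± 400 TPM (SD, n = 7) after control ADC to 92.9 ± 75.8 after EV. The glucose transporter gene SLC2A1 fell by 2.05 ± 0.39, the collagen prolyl hydroxylase gene P4HA1 by 1.74 ± 0.28, the pyruvate dehydrogenase kinase gene PDK1 by 1.58 ± 0.29 and the histone demethylase gene KDM3A by 1.15 ± 0.21. EGLN3, an oxygen-sensing prolyl hydroxylase (−2.16 ± 0.51), ANGPTL4, an inhibitor of lipoprotein lipase (−2.29 ± 0.48), and NDUFA4L2, a mitochondrial protein gene (−3.46 ± 0.73), fell as well. Of the 26 measured members of the hypoxia list, 23 fell and none rose (25 fell when adjusted over the list alone). The list was called lower than other genes by camera with its preset correlation (adjusted p = 8.5e-16; adjusted p = 0.346 with an estimated correlation). Fry, which tests the list against no change, gave an adjusted p of 0.00069. The mitochondrial percentage differed between the same groups, at 7.18 ± 2.72 after EV and 2.32 ± 1.02 after control ADC in human transcripts (SD, n = 7). In EV 3 the levels of P4HA1, PDK1 and SLC2A1 were 47.7, 10.2 and 530.5 TPM, above those of the other EV tumours.

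The lists of mesenchymal and epithelial genes had medians of opposite sign between EV and control ADC (−0.98 and 0.60), though most members of each were not called. Of 22 mesenchymal and matrix genes, 9 fell and none rose (11 fell adjusted over the list alone). They included VIM, the intermediate filament of mesenchymal cells (−2.10 ± 0.56, SE), SNAI2, a repressor of epithelial genes (−1.65 ± 0.32) and the integrin gene ITGA5 (−1.50 ± 0.31). The list was called lower (camera, adjusted p = 1.4e-05; adjusted p = 0.447 with an estimated correlation; fry, adjusted p = 0.027). The collagenase gene MMP1 (−2.40 ± 0.72) and LGALS1, which encodes galectin-1 (−2.34 ± 0.46), were among the 10 largest falls, with CASP14, a caspase of skin differentiation (−2.39 ± 0.59). VIM lost its call when only the 2 groups were fitted, and MMP1 did so there, without the filter and under both other scalings. Of 28 epithelial and urothelial genes, 7 rose and 1 fell (12 and 1 adjusted over the list alone). The uroplakin genes, which encode the membrane plaques of the bladder lining, rose: UPK2 from 60.6 ± 29.9 to 209 ± 91.3 TPM (SD; log2 1.77 ± 0.37, SE), UPK3B by 1.82 ± 0.39 and UPK3A by 1.93 ± 0.34. IVL, a protein of the cornified envelope, rose by 2.06 ± 0.51. This list was called higher (camera, adjusted p = 4.3e-08; adjusted p = 0.346 with an estimated correlation; fry, adjusted p = 0.079).

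The largest rises of single tumour genes after EV were those of SAA2 (log2 3.60 ± 0.57, SE) and SAA1 (3.22 ± 0.55), acute-phase proteins whose sequences are nearly identical, so that the split between them is uncertain. SAA1 went from 19.8 ± 14.7 TPM (SD, n = 7) after control ADC to 248 ± 190 after EV. Rises of 2.58 or more were also found for the cytidine deaminase gene APOBEC3A (2.91 ± 0.59), PDZK1IP1 (2.91 ± 0.68), the mucin gene MUC4 (2.87 ± 0.50), MSMB (2.78 ± 0.72), the cytochrome P450 gene CYP4B1 (2.62 ± 0.56), LCN2, an iron-siderophore binding protein of innate defence (2.62 ± 0.55), ZACN (2.62 ± 0.55) and the mucosal chemokine gene CXCL17 (2.58 ± 0.61). All 10 were called in each of the 11 alternative settings, which do not include leaving out single libraries. S100A8, which encodes a subunit of calprotectin, rose by 1.99 ± 0.49, and its partner S100A9 had a difference of 1.15 ± 0.38 that was not called (limma, adjusted p = 0.058).

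**Figure D2:**
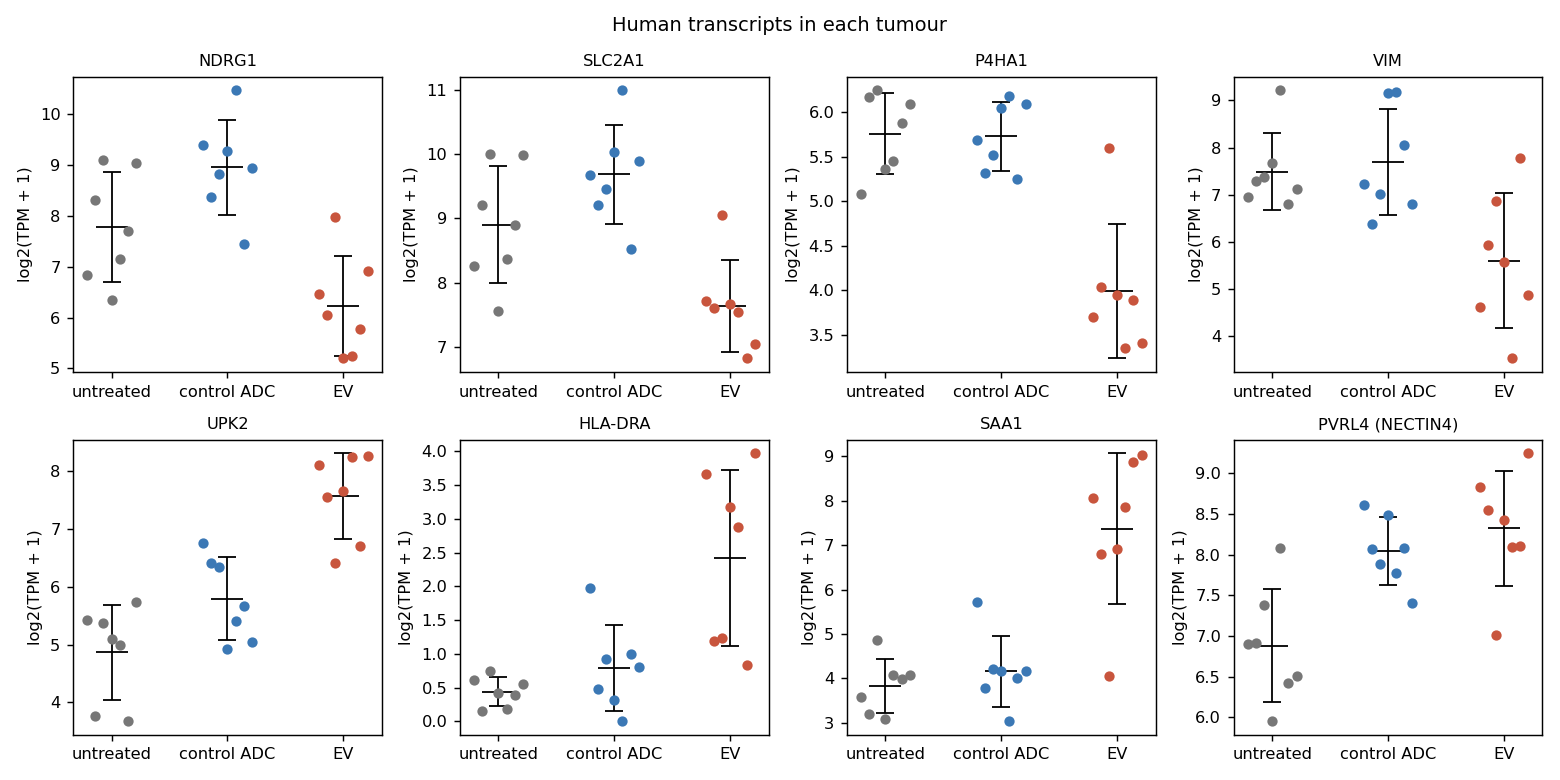
Level of 8 human transcripts in each tumour as log2(TPM + 1); points are tumours, bars the mean and SD of 7 per group. NDRG1, SLC2A1, P4HA1 and VIM were lower and UPK2, HLA-DRA and SAA1 higher after EV than after control ADC, while NECTIN4 differed by 0.28 ± 0.30 (SE) between these groups.

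Both lists of antigen presentation genes were called higher in tumour cells after EV than after control ADC by camera, though not by fry, and few of their members were called. Of 20 MHC class I genes, 5 rose and none fell (5 adjusted over the list alone), among them the class I heavy chains HLA-B (log2 1.08 ± 0.33, SE), HLA-C (0.80 ± 0.23) and HLA-F (0.78 ± 0.24) and the immunoproteasome subunit PSMB10 (0.77 ± 0.21). HLA genes resemble one another, and reads between them may be divided wrongly. Each of these 4 lost its call when only the 2 groups were fitted, HLA-B, HLA-C and HLA-F also without the filter, and HLA-B and HLA-F with the mouse number as a block. The list was called higher (camera, adjusted p = 8.4e-07; adjusted p = 0.383 with an estimated correlation; fry, adjusted p = 0.100). Of 8 MHC class II genes, 2 rose (5 rose and 1 fell adjusted over the list alone): the antigen-processing protease gene CTSS, from 19.4 ± 8.02 to 52.3 ± 34.9 TPM (SD; log2 1.23 ± 0.30, SE), and HLA-DRA (1.63 ± 0.42), which was at 6.31 ± 5.52 TPM (SD, n = 7) after EV and lost its call when only the 2 groups were fitted. That list was called higher too (camera, adjusted p = 0.00011; adjusted p = 0.346 with an estimated correlation; fry, adjusted p = 0.079). The type I interferon list of 42 genes was called higher (camera, adjusted p = 0.00013; adjusted p = 0.588 with an estimated correlation; fry, adjusted p = 0.576) with a median of 0.15, but none of its members was called as higher. Its only called member was EIF2AK2, the double-stranded RNA kinase PKR, which fell by 0.67 ± 0.20 but lost its call without the filter and with the replicate block, and no member was called adjusted over the list alone. IFI6 (0.64 ± 0.20) and ISG15 (0.61 ± 0.23), both interferon-induced, were not called (limma, adjusted p = 0.050 and 0.085), but were called in 7 and 3 of the 11 alternative settings.

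Both lists of cell division genes were called lower after EV than after control ADC by camera, though not by fry, and few of their members were called. Of 40 mitosis genes, 2 fell (15 adjusted over the list alone), the spindle checkpoint gene BUB3 (−0.52 ± 0.14, SE) and the cytokinesis gene ECT2 (−0.48 ± 0.15). Of 37 DNA replication genes, 5 fell (14 adjusted over the list alone), including CCNE2, which encodes cyclin E2 (−1.14 ± 0.30), the origin recognition gene ORC1 (−0.95 ± 0.27), the polymerase subunit gene POLE2 (−0.88 ± 0.25) and the clamp loader gene RFC4 (−0.75 ± 0.22). No member of either list rose, and both lists were called (camera, adjusted p = 6.4e-06 and 4.7e-06; adjusted p = 0.588 for both with an estimated correlation; fry, adjusted p = 0.100 and 0.079). All 6 of these genes lost their calls when only the 2 groups were fitted. BUB3, ECT2, POLE2 and RFC4 also lost them under median-ratio scaling, BUB3, POLE2 and RFC4 under upper-quartile scaling, and ECT2, ORC1, POLE2 and RFC4 without the filter. Against untreated tumours the replication list had a mean of 0.56 after control ADC and −0.05 after EV, and the mitosis list 0.36 and −0.26. The median of all human genes was 0.46 and 0.34. Of 23 cholesterol synthesis genes, 2 fell (2 adjusted over the list alone), the sterol carrier gene STARD4 (−1.04 ± 0.22) and IDI1, an enzyme of isoprenoid synthesis (−0.74 ± 0.17), and that list was called lower (camera, adjusted p = 0.017; adjusted p = 0.588 with an estimated correlation; fry, adjusted p = 0.079).

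The other 8 human lists were not called between EV and control ADC, with camera adjusted p from 0.071 to 0.845. Among 30 ER stress genes (adjusted p = 0.845), XBP1, a transcription factor of the unfolded protein response, rose by 0.51 ± 0.16, and DDIT4 (−1.82 ± 0.40), EDEM1 (−0.67 ± 0.18) and DNAJB9 (−0.71 ± 0.21) fell (1 rose and 4 fell adjusted over the list alone). Among 15 danger signal genes (adjusted p = 0.071), S100A8 was the 1 that rose (2 rose and 1 fell adjusted over the list alone). Among 12 tubulin genes (adjusted p = 0.52), which encode the drug's target protein, TUBB6 fell by 0.97 ± 0.29 (1 fell adjusted over the list alone). Among 27 p53 targets (adjusted p = 0.52), CCNG1 (−0.84 ± 0.21) and the death receptor gene FAS (−0.85 ± 0.23) fell (1 rose and 4 fell adjusted over the list alone). Of 28 apoptosis regulators (adjusted p = 0.52), FAS and CASP6 (−0.46 ± 0.13) fell (1 rose and 4 fell adjusted over the list alone). Of 28 NF-kB genes (adjusted p = 0.25), the chemokine gene CXCL6 rose by 0.94 ± 0.29 and the cytokine gene IL1B fell by 1.21 ± 0.31 (1 fell adjusted over the list alone). Of 12 checkpoint ligands (adjusted p = 0.099), C10orf54, now named VSIR, rose by 1.48 ± 0.36 and CD70 fell by 1.61 ± 0.35 (4 rose and 3 fell adjusted over the list alone). For the apoptosis list camera's direction was up while its median was −0.09, and the NF-kB list had a median of 0.03 and a mean of −0.06. Fitting only the 2 groups ended the calls of XBP1, DNAJB9, TUBB6, CCNG1, FAS, CASP6 and CXCL6. Both other scalings ended those of DNAJB9, TUBB6, FAS and CASP6. Leaving out the filter ended those of XBP1, DNAJB9, TUBB6 and CXCL6, the replicate block that of CASP6 and library weights that of CXCL6. Fry called 2 of the 17 human lists, hypoxia and mesenchymal genes.

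In all, 1220 of 12582 human genes differed between EV and control ADC, 326 higher and 894 lower (limma, adjusted p under 0.05). With upper-quartile scaling 547 were higher and 766 lower, and with median-ratio scaling 828 and 515, against a median of all genes of −0.12, −0.08 and 0.00 on the log2 scale, so that the balance of rises and falls depends on the scaling. The count was 571 with only these 2 groups in the fit and 3085 without EV 3, control ADC 7 and untreated 5. With single libraries left out it was 2337 without EV 3, 650 without EV 1, 401 without EV 5, 411 without EV 7, and 671, 575 and 662 without control ADC 2, 4 and 6. Human fold changes in this comparison ran against gene length (Spearman's rho −0.22), and the bearing of that trend on the results above was not tested.

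In host cells, EV against control ADC gave 18 called genes of 13415, 2 higher and 16 lower, while 1964 had an unadjusted p under 0.05. The 6 largest falls were those of Ankrd37, a hypoxia-induced gene (log2 −2.64 ± 0.49, SE, limma, adjusted p = 0.037), Zfp932 (−2.02 ± 0.38), Trmt10a (−2.02 ± 0.41), the potassium channel gene Kcnj8 of pericytes (from 97.6 ± 32.9 to 32.8 ± 41.7 TPM, SD; 17.1 ± 4.17 after EV without EV 3), Msc (−1.87 ± 0.34) and Pdk1, the mouse counterpart of PDK1 (−1.79 ± 0.35). Ankrd37 went from 33.3 ± 16.6 TPM (SD, n = 7) after control ADC to 6.44 ± 8.14 after EV. The 2 genes that rose, Zbtb20 and Gm27232, lie outside the rule for named genes and were picked out after their values were seen. Red cell genes were lower: of 6 erythroid genes none was called over all genes and 4 fell adjusted over the list alone. The haemoglobin genes Hbb-bs (−2.62 ± 0.58) and Hba-a1 (−2.14 ± 0.47) both had an adjusted p of 0.052, and both have near-identical copies. The list was called lower (camera, adjusted p = 0.00046; adjusted p = 0.565 with an estimated correlation; fry, adjusted p = 0.034). The proliferation list of 28 genes was called lower (adjusted p = 0.00051; adjusted p = 0.760 with an estimated correlation; fry, adjusted p = 0.330), with no member called over all genes, Birc5 at −1.23 ± 0.35 and 8 that fell adjusted over the list alone. The pericyte list of 16 genes was called lower (adjusted p = 0.036; adjusted p = 0.760 with an estimated correlation; fry, adjusted p = 0.330), with Kcnj8 the 1 member that fell (1 rose and 3 fell adjusted over the list alone).

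Host lists called higher after EV than after control ADC were those of 12 adipocyte genes (camera, adjusted p = 0.0046), 18 dendritic cell genes (0.015), 43 type I interferon genes (0.015), 19 interferon gamma genes (0.020) and 19 MHC class I genes (0.031). Each of these 5 had an adjusted p = 0.760 with an estimated correlation and a fry adjusted p of 0.809. None of their members was called over all genes. Adjusted over the list alone 1 adipocyte gene, the lipoprotein lipase gene Lpl (1.35 ± 0.32, SE), and 2 dendritic cell genes rose, and no gene of the other 3 lists. Ccr7, a homing receptor of mature dendritic cells, had a difference of 1.46 ± 0.40, and Irf7, an interferon regulator, 0.78 ± 0.40 (limma, adjusted p = 0.079 and 0.38). Fry called 1 of the 24 host lists, that of erythroid genes. The other 16 host lists were not called (adjusted p from 0.054 for MHC class II to 0.973 for T cell costimulation). In endothelial cells the junction gene Cldn5 (−1.48 ± 0.35), Egfl7 (−0.99 ± 0.24) and Ecscr (−1.17 ± 0.29) had adjusted p of 0.052, 0.056 and 0.056, and 3 of 21 endothelial genes fell adjusted over the list alone (camera, adjusted p = 0.32). The macrophage list of 27 genes (0.10), in which Siglec1 differed by 1.39 ± 0.47, and those of monocytes (0.10), NK cells (0.061), T cells (0.18), mast cells (0.19), fibroblasts (0.19), alternatively activated macrophages (0.18), phagocytosis (0.26), skeletal muscle (0.60), skin epithelium (0.966), B cells (0.62), chemokines (0.79), neutrophils (0.91) and T cell costimulation had no called member over all genes. Adjusted over the list alone 1 chemokine gene fell, and 1 costimulation gene rose and 1 fell. For neutrophils, chemokines and costimulation camera's direction was up and the median below 0. The 18 calls became 0 in a fit of only these 2 groups and with the mouse number as a block, where none of the named genes held. They became 571 without the 3 out-of-place libraries. With 1 library left out they ranged from 1 (without control ADC 2, for example) to 700 (without EV 3). With upper-quartile scaling 4 genes were higher and 0 lower, and with median-ratio scaling 5 and 1.

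**Figure D3:**
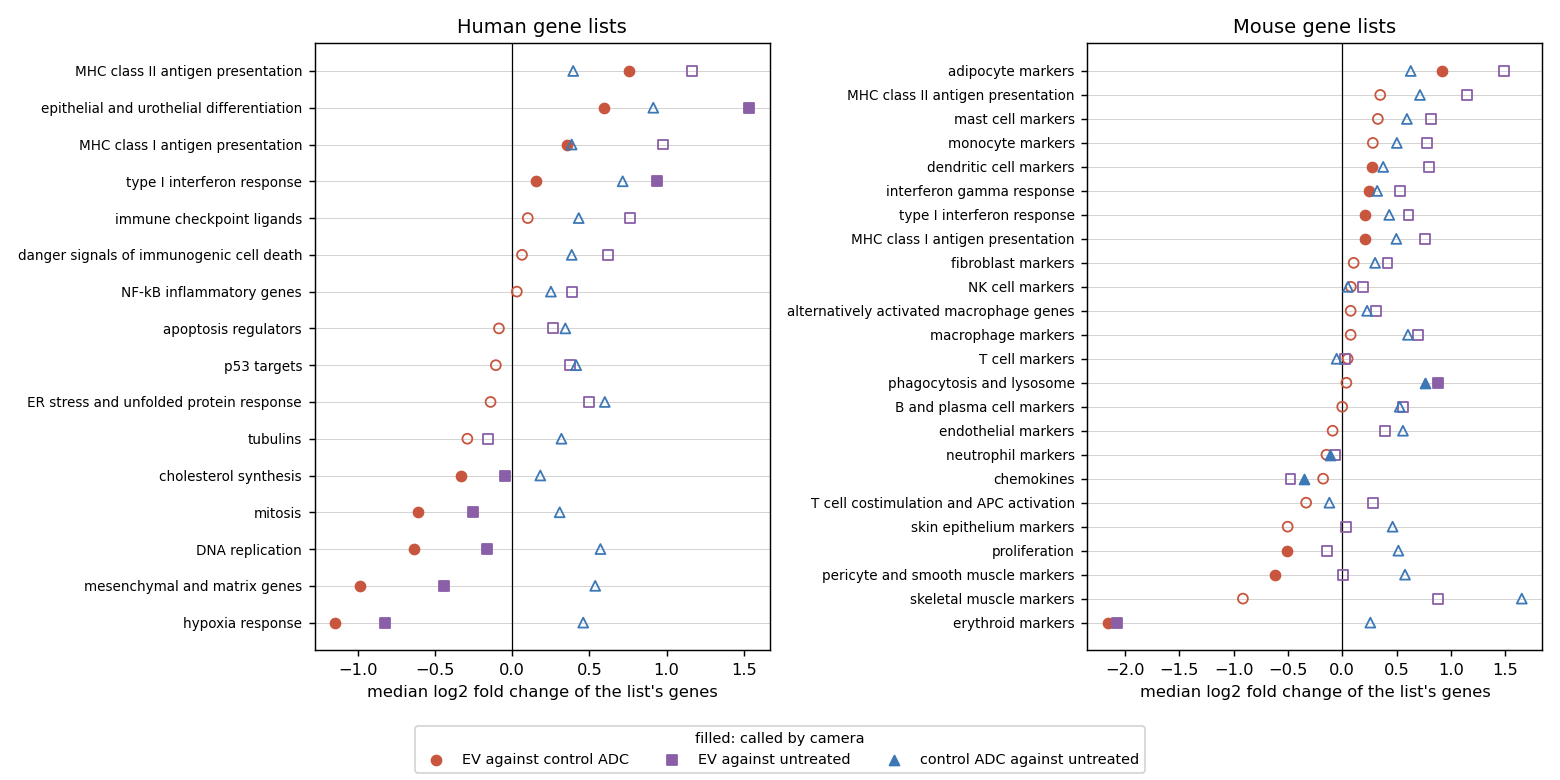
Median log2 fold change of 16 human (left) and 24 mouse (right) gene lists in the 3 comparisons, marked by shape; filled symbols are lists called by camera with the preset correlation. In EV against control ADC the human hypoxia list has the lowest median of the human lists (−1.15) and the mouse erythroid list the lowest of the mouse lists (−2.15).

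In tumour cells of EV against untreated tumours, epithelial genes rose: 22 of 28 were higher and 1 lower (22 and 1 adjusted over the list alone), with KRT13, a keratin of stratified epithelium, going from 440 ± 131 to 1876 ± 699 TPM (SD, n = 7; log2 2.07 ± 0.23, SE), UPK3B up by 3.07 ± 0.39 and GRHL3, an epithelial transcription factor, up by 2.51 ± 0.34. Type I interferon genes rose, 31 of 42 with none lower (31 adjusted over the list alone), among them IFIT2 (2.30 ± 0.44) and IRF7 (1.11 ± 0.20). Hypoxia genes fell, 15 of 26 with none higher (15 adjusted over the list alone), including P4HA1 (−1.77 ± 0.28), the mitophagy gene BNIP3 (−1.51 ± 0.25) and ANKRD37 (−1.92 ± 0.34). Of 40 mitosis genes 15 fell and 2 rose (12 and 2 adjusted over the list alone), with CDK1, the mitotic kinase, at −1.36 ± 0.31 and the kinetochore gene NUF2 at −1.22 ± 0.27. Of 37 replication genes 10 fell and 5 rose (10 and 4 adjusted over the list alone), with CCNE2 at −1.36 ± 0.30 and RFC4 at −1.03 ± 0.22. Of 22 mesenchymal genes 5 fell and 1 rose (4 and 1 adjusted over the list alone), with SNAI2 at −1.40 ± 0.32 and MMP1 at −2.77 ± 0.72. Of 23 cholesterol genes 7 fell and 6 rose (7 and 6 adjusted over the list alone), with STARD4 at −1.72 ± 0.22, IDI1 at −1.10 ± 0.17 and MVD, an enzyme of the same pathway, at 1.33 ± 0.27. These 7 lists were called (camera, adjusted p = 0.00016, 0.0023, 1.1e-08, 0.00016, 0.012, 0.0023 and 0.024 in the order given), each with adjusted p = 0.904 with an estimated correlation. Fry called the first 3 (adjusted p = 2.3e-05, 0.0051 and 0.0055) and not the others (0.389, 0.704, 0.241 and 0.419).

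The largest rises in EV against untreated tumours were those of the myosin gene MYH14 (log2 4.53 ± 0.57, SE), BCAS1 (4.33 ± 0.56), the mucin gene MUC1 (4.15 ± 0.54) and KLHDC7B (4.13 ± 0.74). The largest falls were those of LGALS1 (−3.43 ± 0.46), NDUFA4L2 (−3.22 ± 0.73), AMTN (−3.12 ± 0.97) and SMR3B (−2.91 ± 1.16). AMTN lost its call with library weights and SMR3B with these, without the filter and without the 3 out-of-place libraries. The 10 other human lists were not called by camera (adjusted p from 0.131 to 0.942). Among them 12 of 20 MHC class I genes rose and 1 fell (12 and 1 adjusted over the list alone), with HLA-E at 1.31 ± 0.23, and 6 of 8 MHC class II genes rose (7 adjusted over the list alone). Heat shock genes HSPA1A (1.93 ± 0.32) and HSPA1B (2.11 ± 0.35), near-identical copies, were among 9 danger signal genes of 15 that rose, with 1 lower (9 and 1 adjusted over the list alone), and CEBPB (1.61 ± 0.23) was among 16 ER stress genes of 30, with 2 lower (16 and 2 adjusted over the list alone). For p53 targets and NF-kB genes camera's direction was down and the median above 0. Fry, which makes no comparison with other genes, called 11 of the 17 human lists here. Among these were MHC class I, MHC class II and ER stress genes (fry, adjusted p = 0.0051 each). Of 12582 human genes 5658 were higher and 2007 lower in EV than in untreated tumours, with a median of all genes of 0.34 on the log2 scale. With upper-quartile scaling 3645 were higher and 4416 lower, with median-ratio scaling 3936 and 4098, and with the ribosomal protein percentage as a covariate limma called no gene (1009 at an unadjusted p under 0.05).

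In host cells, genes of phagocytosis and lysosomes rose in EV against untreated tumours, 14 of 24 with none lower (15 adjusted over the list alone). They included the endocytic receptor gene Lrp1 (log2 1.55 ± 0.27, SE), the receptor kinase gene Axl (1.65 ± 0.35) and its ligand Gas6 (1.53 ± 0.32), and the list was called (camera, adjusted p = 0.018; adjusted p = 0.958 with an estimated correlation; fry, adjusted p = 0.020). Its adjusted p was 0.056 without the 3 out-of-place libraries. Of 27 macrophage genes 12 rose and none fell (13 adjusted over the list alone; camera, adjusted p = 0.087), with Csf1r, the macrophage growth factor receptor, going from 36.7 ± 24.1 to 218 ± 138 TPM (SD, n = 7; log2 2.48 ± 0.49, SE). Of 6 erythroid genes 3 fell (4 adjusted over the list alone), with Hbb-bs at −3.25 ± 0.58 and Hba-a1 at −1.94 ± 0.47, and the list was called lower (adjusted p = 0.0086; adjusted p = 0.958 with an estimated correlation; fry, adjusted p = 0.020). The chemokine genes Ccl7 (−2.10 ± 0.50) and Ccl2 (−1.44 ± 0.40) fell, within a list of 26 that was not called (adjusted p = 0.087; 5 fell and 2 rose, also adjusted over the list alone). Among the largest rises were those of the calcium pump gene Atp2b4 (3.35 ± 0.61), Lims2 (3.12 ± 0.43) and Gpnmb (2.99 ± 0.57), and the largest falls those of Gkn1 (−3.66 ± 0.67), Kcne3 (−3.60 ± 0.56), Ankrd37 (−3.54 ± 0.49) and Hbb-bs. The 22 host lists not called had camera adjusted p from 0.087 to 0.980, and in 6 of them camera's direction and the median differed in sign. Fry, which makes no comparison with other genes, called 5 of the 24 host lists. These included monocyte (fry, adjusted p = 0.038), dendritic cell (0.038) and B cell markers (0.046). Of 13415 mouse genes 3302 were higher and 1344 lower (median of all genes 0.29). With upper-quartile scaling 2757 were higher and 1905 lower, with median-ratio scaling 2374 and 2235, and with the ribosomal protein covariate limma called none (705 at an unadjusted p under 0.05), and Csf1r (−0.11), Axl (−0.077) and Hba-a1 (0.28) turned in direction.

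In tumour cells of control ADC against untreated tumours, 20 of 30 ER stress genes rose and none fell (20 adjusted over the list alone), with the chaperone genes HSPA5 at 0.80 ± 0.17 (SE, not called under upper-quartile scaling) and HYOU1 at 1.45 ± 0.30. Of 28 epithelial genes 17 rose (20 adjusted over the list alone), among them the cadherin gene CDH1, from 44.8 ± 18.3 to 143 ± 61.0 TPM (SD, n = 7; log2 1.65 ± 0.34, SE), KRT13 (1.38 ± 0.23) and the urothelial transcription factor gene GATA3 (1.55 ± 0.31). Interferon genes rose in 25 of 42 cases (26 adjusted over the list alone), with OAS3 at 1.78 ± 0.38 and MX1 at 1.72 ± 0.38. Of 27 p53 targets 11 rose (8 adjusted over the list alone), including PHLDA3 (1.06 ± 0.19) and the death gene BBC3 (1.02 ± 0.27, not called under median-ratio scaling). Of 37 replication genes 16 rose (15 adjusted over the list alone), of 40 mitosis genes 11 (9), of 26 hypoxia genes 9 (6) and of 22 mesenchymal genes 7 (3), and none of these fell. Among all 12582 human genes 6387 were called higher, and the median of all human genes was itself 0.46 higher. Camera called none of the 17 human lists relative to other genes (adjusted p from 0.271 to 0.876), with a direction that differed in sign from the median for 12. Fry, which makes no comparison with other genes, called 9, including the first 4 named here.

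The largest rises after control ADC were those of the myosin genes MYH14 (log2 2.73 ± 0.57, SE) and MYH9 (2.54 ± 0.50), HNRNPUL2-BSCL2 (2.53 ± 0.52), a readthrough gene whose reads overlap its neighbours and whose value is therefore uncertain, and HELZ2 (2.39 ± 0.46). The largest falls were those of TINAG (−1.54 ± 0.55), SELM (−1.26 ± 0.34), LGALS1 (−1.09 ± 0.46) and SRGN (−1.05 ± 0.45). TINAG lost its call with library weights, LGALS1 without the filter, and SRGN with a pseudocount of 0.1, without the filter, with weights and without the 3 out-of-place libraries. In host cells phagocytosis genes rose, 12 of 24 (14 adjusted over the list alone), with Dock2 at 1.78 ± 0.38, Gas6 at 1.45 ± 0.32 and Axl at 1.28 ± 0.35, and the list was called (camera, adjusted p = 0.011; adjusted p = 1.00 with an estimated correlation; fry, adjusted p = 0.050). The neutrophil list of 18 was called lower (adjusted p = 0.021; adjusted p = 1.00 with an estimated correlation; fry, adjusted p = 0.873), with the calprotectin genes S100a8 (−0.83 ± 0.27) and S100a9 (−0.93 ± 0.26) as the 2 that fell (1 adjusted over the list alone). The list of 26 chemokines was called lower (adjusted p = 0.0019; adjusted p = 0.639 with an estimated correlation; fry, adjusted p = 0.531), although its 1 called member, Cx3cl1, rose by 1.44 ± 0.35 (1 adjusted over the list alone) and Ccl2 differed by −0.99 ± 0.40 (limma, adjusted p = 0.082). Under upper-quartile scaling camera called none of these 3 lists. The other 21 host lists had camera adjusted p from 0.164 to 1.00. The largest host rises were those of Srp54a, which has near-identical neighbours (2.64 ± 0.66), Serpina3n (2.21 ± 0.63), Cd300lh (2.20 ± 0.49) and Bcas3 (2.17 ± 0.39), and the largest falls those of Lyrm9 (−2.50 ± 0.71), Ifitm6 (−1.97 ± 0.59), Cmc4 (−1.76 ± 0.44) and Rac3 (−1.53 ± 0.48). Serpina3n lost its call under both other scalings, Axl under upper-quartile scaling, S100a8 without the filter and Ifitm6 without the 3 out-of-place libraries. Rac3 lost it with a pseudocount of 0.1, without the filter, with only the 2 groups and with the replicate block. Of human genes 6387 were higher and 712 lower, which became 3159 and 2880 with upper-quartile and 2923 and 3155 with median-ratio scaling. Of mouse genes 2398 were higher and 223 lower (median of all genes 0.36), which became 495 and 781, and 618 and 828. With the ribosomal protein covariate limma called no gene of either species (569 human and 637 mouse genes at an unadjusted p under 0.05).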

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

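The library measures, and the tests on the 3 out-of-place libraries, the ribosomal protein trend, the host cells, gene length in EV against untreated and both label exchanges, were chosen after the results were seen; the tests on other splits, on human reads assigned to mouse genes, on gene length in control ADC against untreated and on transcripts shared by both species were not.

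Other splits of the 14 libraries of each comparison were fitted, 100 per comparison with the real one. In human genes only the real split, 1 of 100, called as many genes: 1220 in EV against control ADC (highest other 1), 7665 in EV against untreated (highest other 6174) and 7099 in control ADC against untreated (highest other 6983). In mouse genes it was 3 of 100 for EV against control ADC (18 genes, highest other 112), 1 of 100 for EV against untreated (4646, highest other 2278) and 3 of 100 for control ADC against untreated (2621, highest other 4512). Each share thus lay under 0.05, without adjustment over the counts. This does not exclude chance for the mouse counts that other splits reached as well. Single splits called as many as 112 mouse genes against 18, or 4512 against 2621, while the median over the other splits was 0. How close those single splits lay to the real groups was not recorded. They therefore cannot tell a structure besides the groups from the groups themselves.

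Hypoxia genes were lower in EV than in control ADC tumour cells. Leaving out the 3 out-of-place libraries gave a median of −1.22 (camera, adjusted p = 4.8e-12) and the ribosomal protein covariate −1.09 (adjusted p = 8.3e-09), against these libraries or that trend as the whole cause. Both p-values used the preset correlation. In the main fit camera did not call the list with an estimated correlation (adjusted p = 0.346). The 25 measured mouse orthologues had a median of −0.80 (camera, p = 1.5e-11; p = 0.031 with an estimated correlation), with 23 lower in direction, 2 called lower and none called higher, so a lower hypoxia response may extend to the host cells. Human reads assigned to mouse genes are argued against, because the median mouse to human ratio of the epithelial list was 0.0051 of that of the hypoxia list (0.0059 over 1.16). The mitochondrial percentage, which was higher in EV than in control ADC tumours (7.18 against 2.32 in human, 16.1 against 5.37 in mouse transcripts), was not tested as a cause, and it stays open, as does a difference in oxygen supply, tumour size or viable tissue, which was not measured.

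Untreated tumours were richer in ribosomal protein transcripts than both ADC groups. The human and mouse fold changes of control ADC against untreated correlated across 9645 equally named genes (Pearson's r = 0.55). A cause acting on transcripts of both species, in the tissue or in the handling of the RNA, may be at work. Reads assigned to the wrong species were not tested as a source of this correlation. Gene length correlated with the human fold change with a Spearman coefficient of 0.18 in control ADC against untreated. That lies between the bounds set beforehand, which leaves a length bias open there. In EV against untreated the coefficient was 0.023, which argues against a length bias there. In EV against control ADC, which is outside this pattern, it was −0.22, so that longer genes tended to be lower after EV. Whether that trend bears on the genes and lists of EV against control ADC was not tested. Whether a few abundant genes shifted the others stays open, since with median-ratio scaling 3635 of the 7099 human genes called in control ADC against untreated kept their call and sign. A biological effect of MMAE, which both conjugates carry, is confounded with the groups here and was not tested.

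The human profiles of EV 3, control ADC 7 and untreated 5 lay with another group, and those of EV 2 and EV 4 did so by smaller margins. Only the first 3 were left out in the setting without out-of-place libraries. That choice, made on the profiles, favours differences between the groups. The mean Pearson's r of EV 3 was 0.971 with untreated and 0.928 with EV libraries, that of control ADC 7 0.976 with untreated and 0.951 with its own group, and that of untreated 5 0.969 with control ADC and 0.944 with its own group. An exchange of labels between control ADC 7 and untreated 5 stays open. In mouse genes each correlated better with the other group, by 0.026 and 0.00095. However, 3 other control ADC libraries (1, 5 and 6) also correlated better with a group not their own. The H19 row, whose origin is unknown, followed the labels as given. It was 1222870 in control ADC 7, above every untreated library, and 599393 in untreated 5, below every control ADC library. For an exchange of EV 3 with an untreated library the rule set for the test gave no decision. In human genes 0 untreated libraries correlated best with EV. However, EV 2 and EV 4 also correlated slightly better with control ADC (0.968 against 0.959, and 0.963 against 0.962). Every untreated library had its lowest mean r with EV, at most 0.923 (untreated 5, 0.944 with its own group). Human mitochondrial percentages reached 4.07 at most in untreated libraries, below the other EV libraries (5.74 or more). These values argue against such an exchange, though least clearly for untreated 5. Its mouse mitochondrial percentage (8.38) exceeded that of EV 1 (7.82). The H19 row of EV 3 (1133060) lay above every untreated library. Its human mitochondrial percentage (3.32) lay above every untreated library but untreated 5 (4.07). The human ribosomal protein percentage of EV 3 (29.2) lay within the untreated range only because of untreated 5 (22.6). The lowest of the other untreated libraries was at 30.1. A tumour that responded little, or a wrong label from elsewhere, was not tested.

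A library far from the other 6 of its group was found for 47 of 429 groups of values, where chance alone would give 21.45. Of these, 14 fell on control ADC 7 and 11 on EV 3. In EV 3 the high values were ANKRD37 14.7 TPM, DDIT4 442.1, P4HA1 47.7, PDK1 10.2, SLC2A1 530.5, STARD4 15.8 and mouse Kcnj8 127.0, with a ribosomal protein percentage of 29.2 in human and 23.8 in mouse transcripts, and the low ones HELZ2 20.5 and MYH14 15.5. In control ADC 7 the low values were ARHGAP1 25.05, HELZ2 18.2, HNRNPUL2-BSCL2 16.3, HSPA1A 76.6, HSPA1B 54.025, HYOU1 58.3, MVD 19.8, MYH14 4.16, MYH9 47.2, OAS3 45.2, ROCK1 5.71 and mouse Atp2b4 0.517, and the high ones mouse Kcne3 619 and the human ribosomal protein percentage, 32.0.

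Control ADC 5 stood apart with MMP1 2891, SNAI2 65.9, TUBB6 242 and mouse Lyrm9 7.30 (high) and PSMB10 71.3 (low), control ADC 1 with CXCL6 129 and LCN2 588 (high), and control ADC 2 with mouse Gkn1, listed at 0. EV 7 had low ORC1 (1.00) and POLE2 (2.05), and EV 5 low mouse Ccl2 (10.8). Untreated 1 had low IL1B (1.18) and high ZACN (2.32) and mouse Cmc4 (29.0), untreated 2 low CTSS (9.27), untreated 3 high mouse Srp54a (3.10), untreated 4 low mouse Rac3 (5.69), and untreated 7 low BUB3 (184.6) and CCNE2 (15.0). Untreated 5 had high VIM (593), mouse Cx3cl1 (8.32) and human mitochondrial percentage (4.07).

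The H19 row, whose name both species share, was used in no fit. In control ADC 3 it was 5768760, beside 919213 for all human and 998236 for all mouse names. It therefore cannot be the sum of a human and a mouse TPM, and its origin is unknown. The row was above the highest untreated library (897345) in 7 control ADC and 5 EV libraries. Its medians were 376962 in untreated, 1471200 in control ADC and 1491380 in EV libraries, and which species it comes from cannot be read from the table.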

How the results depend on the processing

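Leaving out the 3 out-of-place libraries, the ribosomal protein covariate and median-ratio scaling were chosen after the results were seen; the other settings were planned. The comparison of the mouse share and the fits with it as a covariate were not run, since the table does not hold that share. TPM keep no depth, so what depth limits is unknown. The named human genes with the largest rises and falls in EV against control ADC kept their calls under all 11 alternatives, except MMP1, which lost its call in 4, and VIM, in 1. The 6 named mouse falls each lost theirs in 6 or 7. These 11 alternatives do not include leaving out single libraries, where the calls of named genes were not followed. Causes of the changes below were not tested unless given. Human genes called in EV against control ADC were 571 with only the 2 groups compared (14 libraries), 3086 with library weights, 3085 with the 3 out-of-place libraries left out (all 1220 shared with the same sign) and 3383 with the ribosomal protein covariate; left out singly, control ADC replicates 2, 4 and 6 gave 671, 575 and 662 and EV replicates 1, 3, 5 and 7 gave 650, 2337, 401 and 411. Mouse genes called there were 8 without the filter, 121 at a mean of at least 5 TPM, 4 with upper-quartile and 6 with median-ratio scaling, 745 with weights, 571 without the 3 libraries, 2 with the covariate, and 0 by limma with only the 2 groups and with the replicate block (1964 at an unadjusted p under 0.05 in the original fit). Left out singly, control ADC replicates 1, 2, 3, 4, 5 and 7 gave 9, 1, 101, 1, 2 and 2, and EV replicates 2 to 7 gave 2, 700, 4, 3, 1 and 1. Mouse lists called there were 4 with the covariate. Equal mouse numbers gave no steady sign of pairing. After removing group means, r between equal numbers in this comparison ran from −0.30 to 0.57 in human and −0.24 to 0.23 in mouse genes. Unequal numbers were not compared, so pairing cannot be excluded. In EV against untreated, mouse lists called were 7 without the filter, 6 with weights and 1 without the 3 libraries. In control ADC against untreated, human lists called were 4 without the filter, 1 with weights and 8 with the covariate. Mouse genes called there were 1276 with upper-quartile and 1446 with median-ratio scaling, 4576 with weights, 4672 without the 3 libraries, and 1230 and 1333 without untreated replicates 4 and 6, 1359, 1600 and 3794 without control ADC replicates 1, 6 and 7; mouse lists were 0 with upper-quartile scaling, 1 with median-ratio scaling and 6 with the covariate. With the covariate, whose variance the groups of the 2 comparisons with untreated explain to 0.665 (EV) and 0.546 (control ADC) in human and 0.732 and 0.550 in mouse genes, limma called 0 genes of both species in EV against untreated (1009 human and 705 mouse at an unadjusted p under 0.05) and 0 in control ADC against untreated (569 and 637). The median size of the human log2 fold change went from 0.55 to 0.20 and from 0.50 to 0.17, and the median SE from 0.20 to 0.24 and 0.21; in mouse genes the fold went from 0.57 to 0.33 and from 0.47 to 0.25 and the SE from 0.31 to 0.47 and 0.38, so that the calls ended with smaller folds and larger errors in both species. In that fit PVRL4 (−0.069), Axl (−0.077), Csf1r (−0.11) and Hba-a1 (0.28) reversed in EV against untreated, as did camera's direction for the mouse NK cell (median 0.67) and interferon gamma lists (−0.69), and in control ADC against untreated for the human type I interferon (0.064) and hypoxia (0.65) and the mouse erythroid (1.24), type I interferon (−0.23) and MHC class I (−0.20) lists.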

Other observations

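Some features of the tumours lie outside the comparisons; these genes were picked after their values were seen. Untreated T24 tumours expressed keratins and cadherins of epithelial cells beside mesenchymal genes: the basal keratin gene KRT5 was at 1221 ± 618 TPM (SD, n = 7), KRT13 at 440.4 ± 131, CDH1, which encodes E-cadherin, at 44.8 ± 18.3 and UPK2 at 31.9 ± 15.2, and the fibronectin gene FN1 at 900.1 ± 355, VIM at 213 ± 171 and CDH2, which encodes N-cadherin, at 7.80 ± 7.24. Human and mouse fold changes correlated across equally named genes in EV against untreated (Pearson's r = 0.56) and in EV against control ADC (r = 0.24).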
